A study of Homo sapiens with 8 samples.

How the data were processed

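RNA from 8 cultures was hybridized to Affymetrix HG-U133 Plus 2.0 arrays, which measure transcripts with sets of short oligonucleotide probes. Per the labels, the cultures came from 2 human B-cell leukaemia lines, SUP-B8 and NALM-6, and each line was kept for 72 hours with the vehicle DMSO or with GSK126 at 0.5 uM. The 4 groups hold 2 biological replicates each, and the p-values rest on the labels calling the replicates biological.

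The deposited table holds one log2 value per probe set and array for 54675 probe sets. MAS5 and RMA were used per the submitters' processing notes, with role and version not given in the sources used here. The log2 unit was read from the deposited values themselves: array medians lay between 7.18 and 7.24, minima between 3.15 and 3.28 and maxima between 15.06 and 15.11. The values were therefore taken as normalized between arrays by the authors and were not transformed. Such normalization sets the arrays to one overall distribution, so a change shared by most transcripts would not be seen. No detection calls were used here, and the number of arrays limits the precision. A group whose arrays all lay below their medians of all probe sets was therefore taken as not shown to be above background, a limit chosen after the results were seen. A difference against such a group is given as at least the distance from the other group's mean to the array medians, for the probe set that represents the gene. Where both groups lay below, no size is given.

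Probe sets were named from the platform annotation. Of the 54675 probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were not listed there and stay unnamed here. Symbols were compared through the gene identifier with a RefSeq gene table, in which 41043 were already current and 54 identifiers were absent. Each of the 19775 genes was represented by its probe set with 1 symbol and the highest mean over the 8 arrays. A gene was tested if at least 2 of the 8 arrays lay above that array's median of all probe sets, which left 13161 genes. No genome build was named, so no coordinates are given.

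The test was limma version 3.58.1 in R version 4.3.3, with one mean per group, 4 residual degrees of freedom shared by all groups, and moderated variances. The 4 contrasts were GSK126 minus DMSO in each line, the difference between those responses (SUP-B8 minus NALM-6), and SUP-B8 minus NALM-6 under DMSO. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. With 2 arrays against 2, an exact permutation test of one gene cannot give a two-sided p below 0.333, so all calls rest on the model. Values are log2 differences ± SE from that model, or group means ± SD with n = 2. Python version 3.11.15 prepared the tables.

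The gene lists, 28 in number, were written from general knowledge before the data were examined, as were the designs and the alternatives. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry. With an estimated correlation, camera also rests its p-value on the 4 residual degrees of freedom, which the preset form does not. A call lost there is therefore not by itself a sign of correlated members. Several lists share members, CD40, CD27, XBP1 and CDKN1A among them. Genes named by size are the 15 highest and 10 lowest log2 differences among called genes whose replicates do not overlap between the groups, or 10 and 10 for the comparison under DMSO. From each list up to 4 called members of largest size were named, or, where none was called, members of largest size, and the subunits of PRC2 were always included. Genes outside this rule are marked as chosen after their values were seen.

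The procedure was tested on simulated data for the same 13161 genes, with 100 genes changed at each size. For a log2 change of 0.5 it recovered 94% in the SUP-B8 contrast, 89% in the NALM-6 contrast, 67% for the difference of responses and 93% under DMSO. For a log2 change of 1 it recovered 100%, 100%, 99% and 100%. False calls made up 6.28%, 3.57%, 6.21% and 6.76% of all calls in the same order. The simulated noise was independent between genes and equal in all groups, and most genes were left unchanged. In the data 39.3% of genes were called in the NALM-6 contrast, so these rates need not hold for the arrays.

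Alternatives covered the filter on dim probe sets, the choice of probe set, renewed quantile normalization, centring of each array, the variance prior, the arrays in the fit, a replicate block, a fold threshold and the omission of each array. Values on a log2 scale need no pseudocount, so that alternative was not run. Probe sets with several symbols or none were left out of the gene tests.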

Results

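Gene expression was measured on 8 arrays from 2 lines described as acute lymphoblastic leukaemia, SUP-B8 and NALM-6. Cells had been kept for 72 hours with GSK126 at 0.5 uM or with its vehicle DMSO. GSK126 is a selective inhibitor of EZH2, the enzyme of the Polycomb repressive complex PRC2 that methylates lysine 27 of histone H3, a mark of silenced genes. The study's title concerns an EZH2 substitution linked to raised trimethylation of this lysine, and the labels do not state the EZH2 genotype of the lines. Each of the 4 groups had 2 arrays. Replicate arrays correlated at r = 0.9977 to 0.9982 across probe sets, and arrays of different lines at 0.920 to 0.929. The 3′ minus 5′ difference of the control probe sets, a sign of RNA degradation, lay between -0.07 and 0.02 for ACTB and between -0.14 and -0.11 for GAPDH.

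The transcript of the drug's target, EZH2, was not called in any comparison. Its means were 11.21 ± 0.11 and 11.20 ± 0.03 (SD, n = 2) in DMSO and GSK126 arrays labelled SUP-B8. They were 11.21 ± 0.06 and 11.22 ± 0.03 (SD, n = 2) in those labelled NALM-6. An inhibitor of the enzyme need not alter its transcript, so this does not check the treatment labels.

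The comparison under DMSO shows how the lines differed without the inhibitor. Several genes of early B-cell development were far higher in the arrays labelled SUP-B8, although the median over the 24 tested was 0.99. Without detection calls, means below the array medians are not shown to be above background, so differences against them are given as at least the distance to those medians. CD24 was higher by at least 6.71, VPREB1, a part of the surrogate light chain, by at least 6.15, CD9 by at least 6.22, and DNTT, the terminal transferase of immature lymphocytes, by at least 6.47. In the arrays labelled NALM-6 the DNTT mean was 6.86 ± 0.04 (SD, n = 2), below the array medians, against 13.67 ± 0.13 (SD, n = 2) in those labelled SUP-B8. Genes of mature B cells were higher in the arrays labelled NALM-6. Among them were CCR7 (by at least 5.70), CD86 (by at least 4.19) and MS4A1, which encodes CD20 (-5.31 ± 0.06 in the coded direction, SUP-B8 minus NALM-6), each with adjusted p of 1.60e-09 or smaller.

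NALM-6 is commonly described as a precursor B-cell line that expresses terminal transferase. The DNTT level in the arrays labelled NALM-6 differs from that description, so groups are called arrays labelled SUP-B8 or NALM-6 throughout. Every direction given for a line is that of its label.

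Of 24 tested early B-cell genes, 17 were higher and 5 lower in the arrays labelled SUP-B8 (camera, adjusted p = 0.0136, and adjusted p = 0.320 with an estimated correlation). Of 26 mature B-cell genes, 23 were lower and 1 higher (adjusted p = 1.71e-09, and adjusted p = 0.198 with an estimated correlation). MHC class II genes were lower in 15 of 16, HLA-DQA1 by at least 4.61 (adjusted p = 1.79e-06, and 0.225 as the adjusted p with an estimated correlation). TNF receptor superfamily and NF-kB target genes were lower in 18 of 21, with CD70 at -4.07 ± 0.07 and FAS at -4.02 ± 0.06 (adjusted p = 5.94e-07, and adjusted p = 0.225 with an estimated correlation). MYC-linked ribosome biogenesis genes were higher in 16 of 17, with NOP16 at 2.11 ± 0.05 and MYC at 1.26 ± 0.05 (adjusted p = 0.000270, and adjusted p = 0.225 with an estimated correlation). Interferon response genes were higher in 21 and lower in 6 of 29, with HERC5 higher by at least 3.47 and IFITM1 at -3.20 ± 0.12 (adjusted p = 0.0283, and adjusted p = 0.225 with an estimated correlation). The p53 target genes (11 lower and 4 higher of 18) and the cell-cycle inhibitors and G1 cyclins (10 lower and 2 higher of 15) were called lower at adjusted p = 0.0348 and 0.0446. They had adjusted p = 0.668 and 0.320 with an estimated correlation. CDKN2A, at -4.41 ± 0.09, led the cell-cycle inhibitors, a list whose call was lost without SUP-B8-labelled DMSO replicate 1 (0.0367 to 0.0504 over all omissions of an array). Adjusted over the list alone, the counts were the same in these 8 lists except that 5 p53 target genes were higher.

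**Figure D1:**
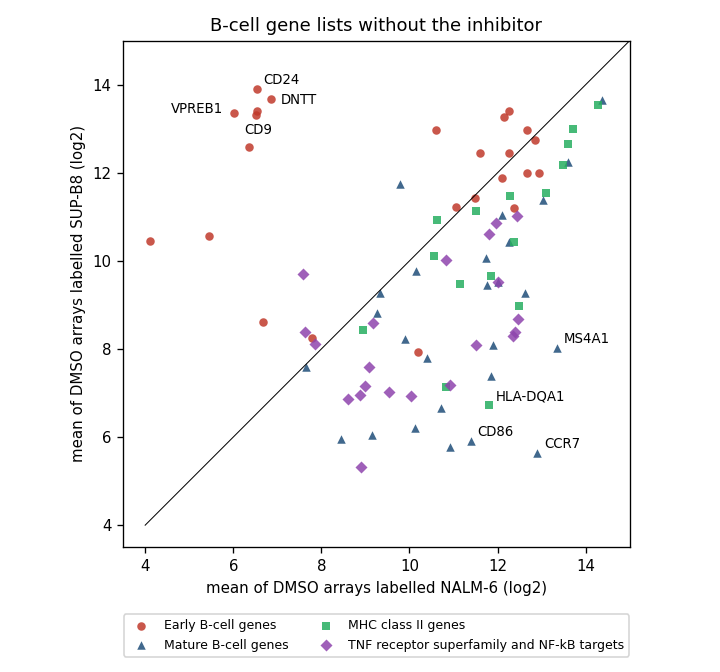
Mean log2 expression of each tested member of 4 gene lists in the DMSO arrays labelled NALM-6 (x axis) and SUP-B8 (y axis), n = 2 arrays each, with the line of equal level. Among early B-cell genes DNTT and VPREB1 lie far above the line, and mature B-cell, MHC class II and NF-kB-linked genes mostly below it.

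In total, 8990 of 13161 genes differed under DMSO at adjusted p under 0.05, 4969 higher and 4021 lower in the arrays labelled SUP-B8. At least 2-fold differences numbered 1365 and 1271. Of these, 1765 were measured on both sides, and 598 others reached 2-fold as bounds against the array medians. All 20 genes named by size lay below the array medians in the line of lower level, so their differences are bounds and have no order. The arrays labelled SUP-B8 were higher by at least 5.80 for GLUL, the glutamine synthetase gene, by at least 5.77 for the signal transducer SMAD1 and by at least 4.96 for MPPED2. For LGR5, CRY1, NRIP1, MYLK and PDGFRA these bounds lay between 4.20 and 5.02. The same arrays were lower by at least 5.65 for RGS13, a regulator of G-protein signalling in germinal-centre B cells, by at least 5.47 for PTPRC, which encodes CD45, and by at least 5.38 for SAMSN1. For MARCKS, PRDX2, LY75, BCL2A1, DMD, MDFIC and BASP1 the bounds lay between 4.43 and 6.57. With the mean of a gene's probe sets, differences kept their direction and call but were smaller for several of these: 4.87 for GLUL, 2.33 for MYLK, 2.08 for PDGFRA, -4.81 for SAMSN1, -4.58 for PTPRC, -4.88 for MARCKS, -2.32 for PRDX2, -3.16 for DMD and -3.79 for BASP1. The same held for CD9 (2.54) and NOP16 (1.05). Groups did not overlap in 81.1% of genes, where chance gives 33.3%. Among PRC2 subunits, JARID2 (0.84 ± 0.06) and MTF2 (0.62 ± 0.07) were higher in the arrays labelled SUP-B8. RBBP7 (-0.60 ± 0.05), PHF1 (-0.41 ± 0.06), AEBP2 (-0.38 ± 0.05), EZH1 (-0.35 ± 0.05), EED (-0.34 ± 0.05) and SUZ12 (-0.27 ± 0.05) were lower. EZH2 (-0.00 ± 0.06), RBBP4 (0.02 ± 0.05) and PHF19 (0.14 ± 0.06) were not called. For PHF19, the mean of its probe sets gave a call in the other direction, at -0.24. Without SUP-B8-labelled DMSO replicate 1, PHF19 was called higher, at 0.21. The other probe sets of AEBP2 and EED differed by -3.09 and -2.50, and the means of their probe sets were -1.74 and -1.42. Those of JARID2 and MTF2 were 0.49 and 0.39.

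The response of the arrays labelled SUP-B8 to GSK126 was small and mostly upward. RGS1, a regulator of G-protein signalling in activated B cells, rose by 2.26 ± 0.14 (adjusted p = 8.03e-04), from 5.77 ± 0.37 to 8.03 ± 0.00 (SD, n = 2). The first of these lay below the array medians, so the rise is shown only to be at least 0.83. Its other 2 probe sets differed by 0.05 and 1.07, and the mean of all of them by 1.13. CD96, an immunoglobulin-family receptor of lymphocytes, rose by 1.45 ± 0.09 (adjusted p = 8.26e-04). MS4A1 rose by 1.07 ± 0.06 (adjusted p = 5.15e-04). The transcription factor TOX rose by 1.04 ± 0.05 (adjusted p = 4.83e-04), and its other probe set differed by -0.10 (mean 0.47). The falls were under 1 log2 unit and included the oestrogen receptor GPER1 (-0.55 ± 0.05, adjusted p = 4.01e-03).

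Altogether 296 of 13161 genes were called, 252 higher and 44 lower, and 2198 had an unadjusted p under 0.05. Of the called genes, 7 rose at least 2-fold and 0 fell at least 2-fold by limma, and 5 of the 7 were measured on both sides. The arrays did not overlap between the treatments in 49.5% of genes, where chance gives 33.3%. Further rises measured on both sides were those of SNTG2-AS1 (1.10 ± 0.07), MTSS1 (1.04 ± 0.11), COL27A1, CD99, OTUD1 and TMEM170B, the last 4 between 0.77 and 0.89. SMCO4 and ZIC2 rose from below the array medians, by at least 0.21 and 0.45. For MTSS1 the 4 other probe sets gave -0.04 to 0.09. The further falls measured on both sides, IGHV5-78, KANK2 and GPR18, lay between -0.46 and -0.42, and SPINK13 fell below the array medians. In 25 of the 296 called genes both levels lay below the array medians, and in 21 others 1 did. Among those named by size, both did for CDC42EP3, MEIS2 and SAMSN1, called higher, and for RASGRP3, EBI3, CYSLTR1, TRIM55 and NIBAN1, called lower, so no size is given for these. When probe sets of a gene were averaged, COL27A1 (0.46), CD99 (0.52), OTUD1 (0.28) and KANK2 (-0.23) stayed called at smaller size. CDC42EP3, SAMSN1, RASGRP3, CYSLTR1 and NIBAN1 lost their call. Of the raised genes, 46 were at least 2 log2 units more abundant in the arrays labelled NALM-6 under DMSO. MS4A1 averaged 13.34 ± 0.01 there against 8.03 ± 0.10 (SD, n = 2). SAMSN1 averaged 12.58 ± 0.01 against 4.27 ± 0.07 (SD, n = 2).

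Mature B-cell genes rose in 5 of 26 tested in the arrays labelled SUP-B8, with 0 lower (camera, adjusted p = 0.000434, and adjusted p = 0.490 with an estimated correlation). Beside MS4A1 these included the immunoglobulin heavy chain IGHD (0.64 ± 0.06), the transcription factor SPIB (0.53 ± 0.06) and, with both levels below the array medians, the B-cell adaptor BANK1. Plasma-cell genes rose in 3 of 14, namely the immunoglobulin joining chain JCHAIN (0.55 ± 0.09), the syndecan SDC1 (0.40 ± 0.08) and, with both levels below the array medians, the elongation factor ELL2. The list had adjusted p = 0.0455, and adjusted p = 0.708 with an estimated correlation. Of 24 genes that cancer studies name as silenced by PRC2, 13 were tested, and the filter on dim probe sets can leave out silent genes. Among the 13, KLF2 (0.70 ± 0.08) and the death receptor TNFRSF21 (0.38 ± 0.07) rose and 0 fell (adjusted p = 0.0285, and adjusted p = 0.490 with an estimated correlation). Adhesion and migration genes rose in 2 of 22, CD99 (0.81 ± 0.10) and the integrin ITGA6 (0.67 ± 0.09), with adjusted p = 0.0495, and adjusted p = 0.729 with an estimated correlation. MHC class II genes (median 0.08 over 16) and PRC1 subunits (median 0.05 over 15) were called upward as lists at adjusted p = 0.0285 and 0.0495 with 0 members called. Here the values were adjusted p = 0.708 and 0.729 with an estimated correlation. Adjusted over the list alone, the higher and lower members were 7 and 2 for mature B-cell genes, 4 and 0 for plasma-cell genes and 4 and 0 for the PRC2-silenced genes. They were 2 and 0 for adhesion genes, 2 and 0 for MHC class II and 4 and 0 for PRC1. As means of their probe sets, IGHD (0.36), ELL2 and KLF2 (0.39) stayed called and SPIB (0.20) did not. No PRC2 subunit was called by limma, and their differences lay between -0.14 ± 0.07 for MTF2 and 0.10 ± 0.06 for JARID2.

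The count was 28 without GSK126 replicate 1, 72 without GSK126 replicate 2, 94 without DMSO replicate 2 and 143 without DMSO replicate 1 of the arrays labelled SUP-B8. It was 191 with only these 4 arrays in the fit, 160 without a filter on dim probe sets, and 777 (504 higher and 273 lower) with an intensity-trended robust prior. Of the 25 genes named by size, RGS1, CD96, SNTG2-AS1, MS4A1, TOX, MEIS2, ZIC2, OTUD1, SAMSN1 and GPER1 stayed called whichever array was left out. The other 15 lost their call in at least 1 omission, CDC42EP3, RASGRP3 and SPINK13 in 7 of 8, and all of these except SPINK13 lost it without GSK126 replicate 1 of that label. Members named from lists lost their call the same way: BANK1, JCHAIN, SDC1, TNFRSF21, ITGA6, ELL2, KLF2 and SPIB were each lost without GSK126 replicate 1. Calls also ended without a filter on dim probe sets (CDC42EP3, SPINK13, RASGRP3, EBI3, TRIM55, BANK1, JCHAIN, SDC1 and TNFRSF21) and with only these 4 arrays in the fit (CDC42EP3, COL27A1, SPINK13, RASGRP3, EBI3 and ELL2). The replicate number as a block ended those of RASGRP3, EBI3, TRIM55 and TNFRSF21, and renewed quantile normalization those of CDC42EP3, SPINK13, RASGRP3 and TNFRSF21. With all probe sets tested, SPINK13, RASGRP3, SDC1 and TNFRSF21 lost theirs, and with the trended robust prior CDC42EP3 did. Mature B-cell genes as a list were called in all 8 omissions (adjusted p of 2.47e-05 to 0.00702). PRC1 (up to 0.230) and plasma-cell genes (up to 0.0749) were lost without DMSO replicate 1, DMSO replicate 2 or GSK126 replicate 1 labelled SUP-B8, or either GSK126 array labelled NALM-6. MHC class II (up to 0.0724) was lost without the same 3 arrays labelled SUP-B8. The PRC2-silenced genes (up to 0.123) were lost without replicate 2 of either treatment of that label, and adhesion genes (up to 0.185) without any array except DMSO replicate 1 labelled SUP-B8. With the replicate number as a block, the call of mature B-cell genes stayed (adjusted p = 0.000402). Those of MHC class II, plasma-cell and PRC2-silenced genes (0.0530), adhesion genes (0.0586) and PRC1 subunits (0.0597) were lost, and that of the PRC2-silenced genes also without a filter (0.107).

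**Figure D2:**
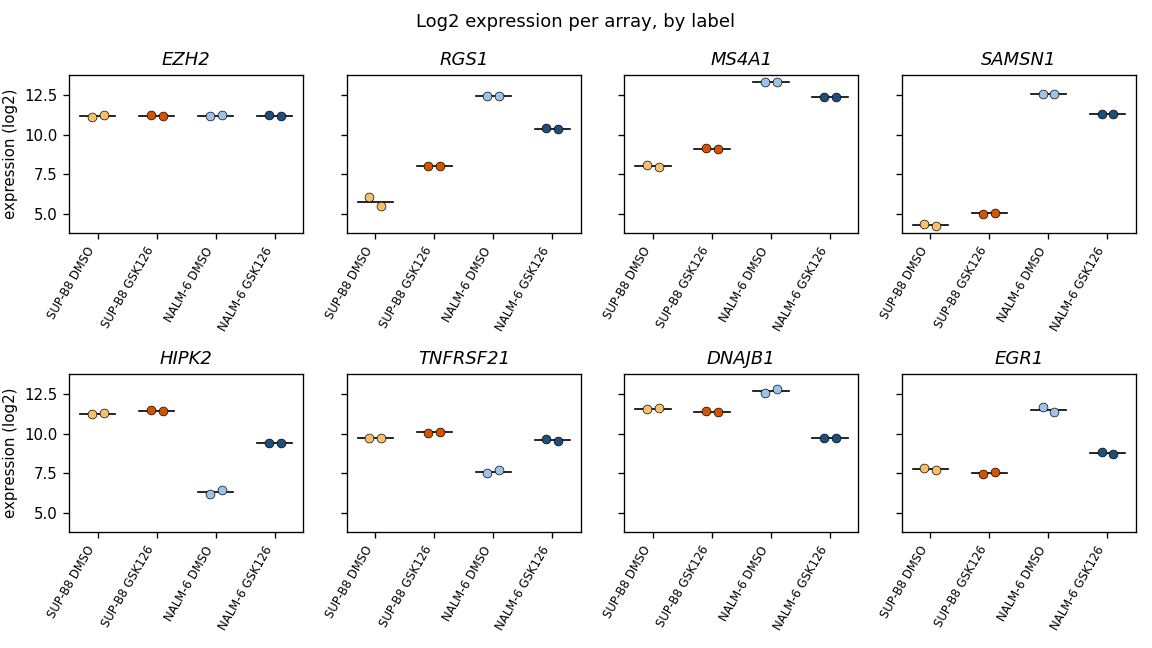
Log2 expression of 8 genes on each of the 8 arrays (points) with the mean of each group of n = 2 (lines), by label. With GSK126, RGS1 rises in the arrays labelled SUP-B8 and falls in those labelled NALM-6, where HIPK2 and TNFRSF21 also rise and DNAJB1 and EGR1 fall.

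GSK126 was followed by far larger changes in the arrays labelled NALM-6. The kinase gene HIPK2 rose by 3.11 ± 0.07 (adjusted p = 2.21e-07), from 6.30 ± 0.15, below the array medians, to 9.42 ± 0.01 (SD, n = 2), so by at least 2.22. CAV1, the main protein of caveolae, rose by 3.04 ± 0.15 (adjusted p = 3.80e-06). The exchange factor PSD3, the lysosomal membrane protein SCARB2 and ARHGAP18 rose from below the array medians, by at least 1.77, 1.72 and 0.74. DNAJB1, a heat-shock cochaperone, fell by 2.99 on the log2 scale (SE 0.08, adjusted p = 4.42e-07), and the immediate-early transcription factor EGR1 fell by 2.75 (SE 0.10, adjusted p = 1.26e-06). NFKBIE, an inhibitor and target of NF-kB (-2.24 ± 0.05), and RGS1 (-2.08 ± 0.14) also fell, as did the Notch target HES1, by at least 1.07 to below the array medians.

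The called genes numbered 5178 of 13161, 2741 higher and 2437 lower. The majority direction depended on the setting: 2255 were higher and 2621 lower with each array centred on its median. With renewed quantile normalization 3160 were higher and 2407 lower. In the reported fit 194 rose and 91 fell at least 2-fold. Of these, 205 were measured on both sides, and 29 others reached 2-fold as bounds. Without overlap between treatments were 68.8% of genes, where chance gives 33.3%. The fructose transporter SLC2A5, MACROD2 and TENT5C rose by 2.03 to 2.22. From below the array medians, ABCB4 rose by at least 1.54, GIMAP2 by 1.07, DNAJC6 by 1.03, GPRIN3 by 0.62, SPIC by 0.39 and IGHV1-69 by 0.07. LINC02909 fell by at least 1.70 to below them. The other falls were LINC00158 (-2.66 ± 0.22), SLAMF1 (-2.21 ± 0.10), ACTN2 (-2.10 ± 0.09) and the chemokine CCL4 (-2.05 ± 0.07). Of 9 other probe sets of HIPK2, 8 moved the same way, between -0.09 and 1.88 for all 9, and of 3 for MACROD2, 1 did. With the mean of a gene's probe sets, the rises were 0.74 for HIPK2, 1.82 for PSD3, 1.47 for SCARB2, 1.45 for SLC2A5, 1.13 for ABCB4, 0.89 for MACROD2 and 1.08 for DNAJC6, all still called. HES1 (-1.20) and SLAMF1 (-1.47) fell less by that measure. A probe set for ribosomal RNA precursor, RNA45SN5, rose by 2.70 ± 0.06. Control probe sets for the 5′ part and the middle of 28S ribosomal RNA were higher by 1.48 and 0.86, whereas its 3′ probe set differed by -0.06.

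Genes of MHC class I antigen presentation rose in 13 of 15 tested with 0 lower (camera, adjusted p = 6.73e-07, and adjusted p = 0.270 with an estimated correlation), led by the transactivator NLRC5 (1.71 ± 0.07) and the immunoproteasome subunits PSMB9 (1.23 ± 0.06) and PSMB8 (0.87 ± 0.05). Interferon response genes rose in 21 of 29 and fell in 1, with OAS1 at 1.64 ± 0.15, CXCL10 at 1.63 ± 0.18 and SAMD9L at 1.33 ± 0.07 (adjusted p = 5.06e-06, and adjusted p = 0.144 with an estimated correlation). Unfolded protein response genes rose in 14 of 20 and fell in 1, with CREB3L2 at 1.51 ± 0.05, SDF2L1 at 1.41 ± 0.06 and the chaperone HSP90B1 at 1.34 ± 0.06 (adjusted p = 2.62e-05, and adjusted p = 0.502 with an estimated correlation). Plasma-cell genes rose in 10 of 14 and fell in 2, with ELL2 at 1.80 ± 0.09, FKBP11 at 1.66 ± 0.06 and MZB1 at 0.98 ± 0.06, against TNFRSF17 at -0.75 ± 0.13 (adjusted p = 0.00127, and adjusted p = 0.270 with an estimated correlation). Glycolysis genes rose in 8 of 19 and fell in 1, ALDOC rising by 1.10 ± 0.05 and the glucose transporter SLC2A3 changing by -1.02 ± 0.06 (adjusted p = 0.0280, and adjusted p = 0.270 with an estimated correlation).

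TNF receptor superfamily and NF-kB target genes fell in 16 of 21 and rose in 3 (adjusted p = 1.54e-05, and adjusted p = 0.270 with an estimated correlation). NFKBIE, CCL4 and the cytokine LTA (-2.0 ± 0.06) fell most, and TNFRSF21 rose by 1.99 ± 0.07. Mature B-cell genes fell in 14 of 26 and rose in 2, including lymphotoxin beta, LTB (-1.31 ± 0.06), the costimulator CD80 (-1.17 ± 0.11) and MS4A1 (-0.95 ± 0.06), with adjusted p = 0.00217, and adjusted p = 0.270 with an estimated correlation. B-cell receptor and PI3K signalling genes fell in 11 of 21 and rose in 4, among them EGR1, EGR3 (by at least 1.21) and FOS (by at least 0.57) (adjusted p = 0.0122, and adjusted p = 0.496 with an estimated correlation). This call ended without either DMSO array labelled NALM-6 (adjusted p of 0.00241 to 0.10 over all omissions). Proliferation genes fell in 19 of 40 and rose in 3, with PLK1 at -0.46 ± 0.06, CCNB1 at -0.44 ± 0.05 and CCNE1 at 0.68 ± 0.06 (adjusted p = 0.000288, and adjusted p = 0.502 with an estimated correlation). Cell-cycle inhibitors and G1 cyclins fell in 8 of 15 and rose in 2, with GADD45B at -1.61 ± 0.11 and CDKN1A, the p21 gene, at 0.37 ± 0.05 (adjusted p = 0.0280, and adjusted p = 0.341 with an estimated correlation). This call was lost without GSK126 replicate 2 labelled NALM-6 (adjusted p of 0.0233 to 0.0504 over all omissions).

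Adjusted over the list alone, higher and lower members numbered 13 and 0 for MHC class I, 21 and 1 for interferon, 14 and 1 for unfolded protein response, 11 and 2 for plasma-cell and 8 and 1 for glycolysis genes. By the same adjustment they numbered 4 and 16 for NF-kB-linked, 3 and 14 for mature B-cell, 4 and 13 for B-cell receptor, 3 and 20 for proliferation and 2 and 8 for cell-cycle inhibitor genes. The PRC2-silenced genes rose in 3 of 13 and fell in 2 (adjusted p = 0.763), TNFRSF21, IRF4 (0.49 ± 0.05) and CDKN1A being the members that rose. PRC1 subunits rose in 7 of 15 and fell in 4 (adjusted p = 0.238), CBX7 (0.93 ± 0.06) and PCGF2 (0.77 ± 0.05) leading the rises. The list of PRC2 subunits was not called (adjusted p = 0.0703, and adjusted p = 0.588 with an estimated correlation), although it was without a filter (0.0360). Of its 11 members, 5 fell. These were PHF19 (-0.43 ± 0.06), PHF1 (-0.31 ± 0.06), AEBP2 (-0.25 ± 0.05), SUZ12 (-0.21 ± 0.05) and RBBP7 (-0.17 ± 0.05). SUZ12 and RBBP7 lost their call without DMSO replicate 2 or either GSK126 array labelled NALM-6. RBBP7 also lost it with the replicate number as a block, without a filter and with only the groups compared. EZH2 (0.01 ± 0.06) and EED (0.06 ± 0.05) were not called, but the mean of both EED probe sets was called at -1.04, the other probe set differing by -2.14. The mean of the AEBP2 probe sets differed by -0.96. By this measure SUZ12 lost its call (-0.10), and PCGF2 (0.39) and IRF4 (0.26) stayed called. By the same measure CREB3L2 (0.51), LTB (-0.64), CD80 (-0.56) and CCNE1 (0.36) from the lists above stayed called.

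**Figure D3:**
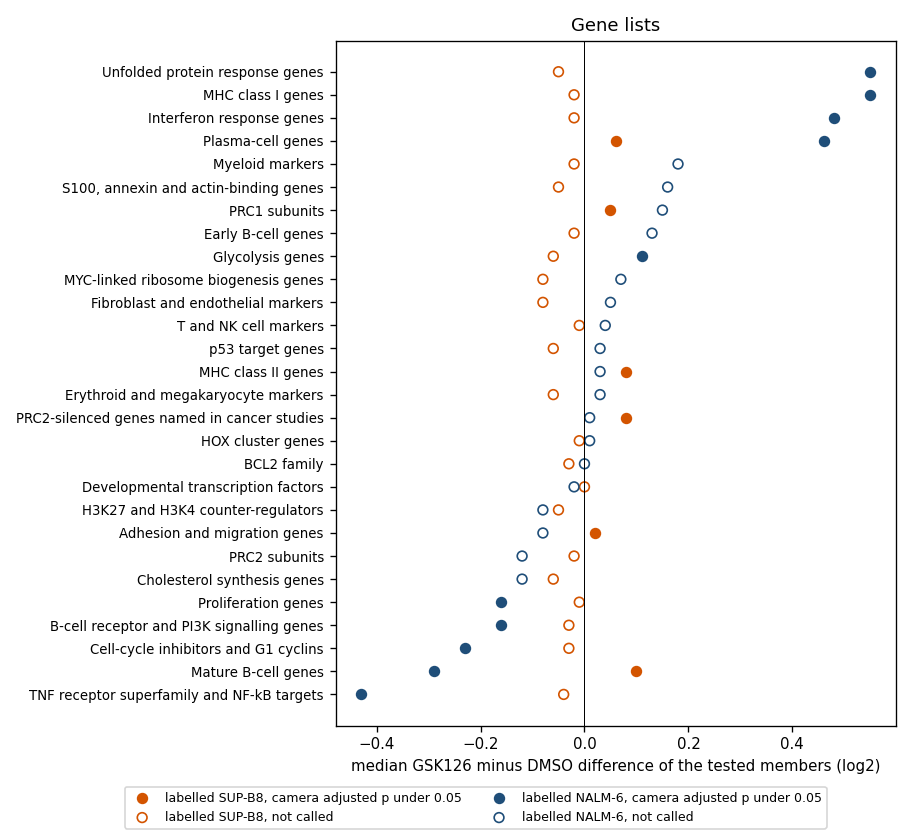
Median GSK126 minus DMSO log2 difference of the tested members of each of 28 gene lists (x axis) in the arrays labelled SUP-B8 (orange) and NALM-6 (blue), n = 2 arrays per group, filled where camera with a preset correlation called the list. Medians reach 0.55 for MHC class I and unfolded protein response genes in the arrays labelled NALM-6 and stay within 0.10 of 0 in those labelled SUP-B8.

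Whether the response itself differed between the lines was tested as an interaction. RGS1 differed by 4.34 ± 0.20 (adjusted p = 1.10e-05), because it rose in the arrays labelled SUP-B8 and fell in those labelled NALM-6. MS4A1 (2.03 ± 0.08, adjusted p = 8.73e-06), SAMSN1 (2.0 ± 0.08, adjusted p = 5.12e-06) and the developmental transcription factor ZIC2 (1.43 ± 0.11, adjusted p = 9.31e-05) likewise moved in opposite directions, each called in both lines. CAV1 (-3.29 ± 0.21), HIPK2 (-2.92 ± 0.10) and SCARB2 (-2.48 ± 0.08) had low values of this difference, rising in the arrays labelled NALM-6 and not called in those labelled SUP-B8. DNAJB1 (2.80 ± 0.12), HES1 (2.49 ± 0.18) and EGR1 (2.47 ± 0.14) fell in the arrays labelled NALM-6 and were not called in the arrays labelled SUP-B8. Averaged over a gene's probe sets, the differences were 2.82 for RGS1, -0.66 for HIPK2, -1.38 for SCARB2 and 1.32 for HES1, all still called. Of the genes named here MS4A1, DNAJB1 and EGR1 had 0 groups below the array medians. The others had 1 to 3, so their sizes rest partly on levels not shown to be above background.

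The interaction was called for 3343 genes, 1440 with the higher and 1903 with the lower response in the arrays labelled SUP-B8, or 43.1% higher. In 3066 of them the response was of larger size in the arrays labelled NALM-6. With each array centred on its median, 1562 were higher and 1379 lower of 2941, or 53.1% higher. By lists, the response differed downward for MHC class I (13 of 15 members lower), interferon response (15 of 29 lower, 1 higher), unfolded protein response (14 of 20 lower, 1 higher), plasma-cell (9 of 14 lower, 2 higher) and glycolysis genes (9 of 19 lower, 1 higher). In that order the adjusted p was 1.90e-07, 2.87e-06, 9.78e-07, 0.0112 and 0.0112. It differed upward for mature B-cell (13 of 26 higher, 0 lower), NF-kB-linked (11 of 21 higher, 3 lower), proliferation (14 of 40 higher, 3 lower), adhesion (8 of 22 higher, 1 lower), B-cell receptor (7 of 21 higher, 3 lower) and cell-cycle inhibitor genes (3 of 15 higher, 2 lower). Here the adjusted p was 1.61e-06, 8.21e-06, 0.000534, 0.00665, 0.0262 and 0.0251. All 11 calls were lost with an estimated correlation, where the adjusted p lay between 0.147 and 0.534. Correlated members do not account for all of this loss. The estimated correlation of the interferon list was 0.00274, below the preset 0.01, yet its unadjusted camera p went from 4.10e-07 to 0.00525. The fewer degrees of freedom of that form also raise p. The B-cell receptor call was also lost without either NALM-6-labelled DMSO array or GSK126 replicate 1 of that label (adjusted p of 0.00709 to 0.244 over all omissions). Adjusted over the list alone, the higher and lower counts were 0 and 13 for MHC class I, 1 and 17 for interferon, 1 and 14 for unfolded protein response, 2 and 10 for plasma-cell and 1 and 10 for glycolysis genes. Those of the upward lists were 16 and 1 for mature B-cell, 14 and 4 for NF-kB-linked, 16 and 3 for proliferation, 8 and 1 for adhesion, 9 and 3 for B-cell receptor and 4 and 2 for cell-cycle inhibitor genes. PHF19 was the 1 PRC2 subunit of 11 with a called difference (0.46 ± 0.08), and the mean of the EED probe sets was called at 1.09. The other probe set of AEBP2 differed by 1.94, where the probe set used gave 0.15 ± 0.07, not called.

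Fold changes in the lines were weakly related across genes, which are not independent replicates (Pearson r = 0.153, Spearman rho = 0.170), and the comparisons share no array. The fold changes in the arrays labelled SUP-B8 had an SD of 0.137, where single replicate arrays of that label differed with an SD of 0.132 (DMSO) and 0.107 (GSK126). Noise therefore lowers these correlations, which do not show that the responses disagree. Of the 296 genes called in the arrays labelled SUP-B8, 199 had the same sign in those labelled NALM-6. The calls of both lines rest on the same fit and the same variance per gene, so genes of low variance are more readily called in both. The Fisher p-values below also treat genes as independent, so they do not measure how far the lines agree. Higher in both were 123 genes, where independent lists would share 52.5 (Fisher's exact test, two-sided, p = 1.95e-23). Chosen after their values were seen, S100A10 (0.48 ± 0.05 in the arrays labelled SUP-B8 and 1.14 ± 0.05 in those labelled NALM-6) and PSD3 (0.52 and at least 1.77) were among them. In the arrays labelled SUP-B8 both lost their call without GSK126 replicate 1 (S100A10, adjusted p = 0.0505), and PSD3 also without either DMSO array. In the arrays labelled NALM-6 the mean of the S100A10 probe sets rose by 0.62. Lower in both were 13 genes, where 8.15 would be shared (two-sided Fisher's exact test, p = 0.0772). Of genes higher in the arrays labelled SUP-B8, 46 were lower in those labelled NALM-6, near the 46.7 of independent lists.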

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

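Of the tests in this part, that of the line names was chosen before its genes had been looked at, although after the early B-cell values were known, and those of replicate spread, spiked controls, ribosomal and heat-shock transcripts, carry-over, shared DMSO arrays and correct line names were chosen after the results they bear on were seen.

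The first pattern is that the early B-cell genes DNTT, VPREB1, IGLL1, CD9, CD24, RAG1, RAG2 and IL7R under DMSO lie below the array medians in the arrays labelled NALM-6 (4.12 to 6.86) and are abundant in those labelled SUP-B8 (10.45 to 13.90), while 5 of the 24 tested early B-cell genes are lower there. One candidate explanation is that the line names were exchanged between the 2 sets of arrays. NALM-6 is known to carry an IGH-DUX4 fusion, and 12 genes known to be raised in leukaemias with that fusion had a median difference under DMSO of 2.09 on the log2 scale (10 higher and 1 lower in the arrays labelled SUP-B8), at percentile 100 of 10000 random lists matched on mean expression. With the 7 genes that lay below the array medians in one line at their bound the median was 1.90, CHST2 being higher by 5.11, DDIT4L by at least 4.52, AGAP1 by at least 3.68 and GPR155 by at least 3.16, and LHFPL2 lower by 2.52. The random lists hold unrelated genes, and other lists of related genes also had medians far from 0 (0.99 for early B-cell and -2.40 for mature B-cell genes). The percentile is therefore not specific to the fusion. A median of 2.09 is what an exchange predicts. The same value, not a second test, argues against a biological difference between lines named correctly. For these the median would be 0 or below. Another stock in place of either line would not be told from an exchange here. Were the names exchanged, the larger response would belong to SUP-B8.

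The second pattern, from the test of the difference between the lines, is that 3343 genes responded differently, mostly with larger changes in the arrays labelled NALM-6. A smaller replicate spread there could not give that line a smaller error, because the fit used the same variance per gene for both lines. The median replicate SD in the arrays labelled SUP-B8 was also only 1.01 times that in the arrays labelled NALM-6, so this cause is argued against. The 18 spiked bacterial control probe sets had GSK126 minus DMSO differences with an SD of 0.0523 in the arrays labelled NALM-6, against 0.347 for the tested genes. For these controls the values argue against hybridization or scanning. They are repeated probe sets for a few transcripts, however. They were also read after normalization between arrays, which removes array-wide differences. A hybridization effect at other intensities or sequences was not tested. A difference in culture handling or RNA preparation cannot be told apart from the treatment, because no other samples separate these: the 28S ribosomal RNA control probe sets differed there by 0.76 on average, by 1.48 for the 5′ and 0.86 for the middle probe set but by -0.06, not called, for the 3′ one, and the 18S controls differed by 0.12 to 0.21 with 0 called, a signal in control probes that the gene comparisons did not use. A difference in EZH2 dependence between the lines stays open and was not tested.

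The third pattern is that of 252 genes raised in the arrays labelled SUP-B8, 46 (18.3%) were at least 2 log2 units less abundant there than in the arrays labelled NALM-6 under DMSO, against 3.84% of all tested genes. Both measures use the same SUP-B8-labelled DMSO arrays. With 1 left out of the fit and used for the level, the shares were 29.4% of 119 and 32.1% of 84 raised genes, at least 7.58 times those of all tested genes. The median replicate SD in the arrays labelled SUP-B8 was 0.0567, far below the cut of 2 log2 units. Noise could hardly move genes across that cut, so the split could hardly have come out otherwise and decides nothing. The tested genes were also not matched on level. Genes dim in every array labelled SUP-B8, such as SAMSN1, were tested only through the arrays labelled NALM-6. Carry-over of RNA or cells of the other line could produce the pattern. The 46 genes imply a median share of 4.95% of the other line, which predicts a median rise of 2.60 for the 33 transcripts at least 6 log2 units less abundant, but their observed median rise was 0.01, 32 of them lay below their prediction, and 5 were called higher. The values therefore argue against carry-over as the whole cause. An effect of the inhibitor on genes expressed in the other line stays open as a hypothesis and was not tested. The share among all genes called lower was not examined. Of the falls named by size, RASGRP3, NIBAN1, EBI3, TRIM55, CYSLTR1 and GPR18 were also at least 2 log2 units less abundant there under DMSO. SPINK13, GPER1, IGHV5-78 and KANK2 were not. The pattern is therefore not shown to be particular to raised genes.

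The response of single genes differed between the lines by the interaction test. The differences above 0 were 4.34 for RGS1, 3.14 for LINC00158, 2.80 for DNAJB1, 2.62 for LINC02909, 2.50 for SLAMF1, 2.49 for HES1 and 2.47 for EGR1. Further values above 0 were 2.21 for BHLHE40, 2.17 for LTA, 2.16 for ACTN2, 2.13 for NFKBIE, 2.05 for CREBRF, 2.03 for MS4A1, 2.0 for SAMSN1 and 2.0 for CCL4. All of these genes fell in the arrays labelled NALM-6. Only RGS1, CREBRF, MS4A1 and SAMSN1 were called in those labelled SUP-B8, where they rose. Differences below 0 were -3.29 for CAV1, -2.92 for HIPK2, -2.66 for RNA45SN5, -2.53 for ARHGAP18, -2.48 for SCARB2, -2.32 for SPIC, -2.31 for PSD3, -2.30 for SLC2A5, -2.25 for IGHV1-69 and -2.23 for GIMAP2. With the mean of a gene's probe sets, SLAMF1 (1.64), BHLHE40 (1.39), PSD3 (-1.41) and SLC2A5 (-1.48) differed less and stayed called. DNAJB1, EGR1, BHLHE40, ACTN2, NFKBIE, MS4A1, RNA45SN5 and SLC2A5 had 0 groups below the array medians, and the other genes here had 1 to 3, so their sizes rest partly on levels not shown to be above background. Lists were called by camera at the preset correlation, and all 11 calls were lost at an estimated one (adjusted p between 0.147 and 0.534), where the test also has fewer degrees of freedom. Their median differences were 0.47 for NF-kB-linked, 0.32 for mature B-cell, 0.18 for cell-cycle inhibitor, 0.15 for proliferation, 0.15 for adhesion and 0.08 for B-cell receptor genes. Below 0 were -0.58 for unfolded protein response, -0.51 for MHC class I, -0.43 for interferon response, -0.39 for plasma-cell and -0.23 for glycolysis genes.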

How the results depend on the processing

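No alternative here was added later. Gene counts in NALM-6-labelled arrays, of the interaction and under DMSO stayed within 1.5 times of their values in every setting except a 2-fold threshold, which left 285, 302 and 2636 genes by construction, and 7 for SUP-B8. The SUP-B8 count was 160 without a filter, 777 with a trended robust prior and 191 with only the groups compared, and the cause was not tested. Leaving out each array gave 28 to 221 genes for SUP-B8 (28, 72, 94 and 143 without GSK126 replicate 1, GSK126 replicate 2, DMSO replicate 2 and DMSO replicate 1 of that label), 3719 to 5322 for NALM-6, 2361 to 3042 for the interaction and 8407 to 8852 under DMSO. A group then keeps a lone array, assumed to vary like the others. The correlation between lines was 0.136 to 0.160 in these runs and 0.132 to 0.153 in the others. An estimated inter-gene correlation left 0 called lists in each of the 4 comparisons, where the preset one called 6, 10, 11 and 8 and fry, which does not compare a list with other genes, called 3, 22, 15 and 23. The estimated form also uses the 4 residual degrees of freedom, so this loss need not be due to correlation alone. Leaving out arrays gave 1 to 5 lists for SUP-B8 (1 without DMSO replicate 2, 2 without GSK126 replicate 1, and 3 without DMSO replicate 1 of that label or without either NALM-6-labelled GSK126 array), 9 to 12 for NALM-6, 10 to 12 for the interaction and 7 to 10 under DMSO. With the replicate number as a block the counts were 213, 4730, 2898 and 8848 genes, and 1 list for SUP-B8. Deviations of same-numbered arrays correlated at -0.0417 and -0.0180 within the lines, and at 0.130 (DMSO) and 0.0363 (GSK126) across them. The labels do not pair the numbers. With the mean of a gene's probe sets, 13 named values changed sign, 5 of them past the threshold in either fit: ALCAM (-0.15), CD47 (-0.03) and EED (-1.04) in NALM-6-labelled arrays, EED in the interaction (1.09) and PHF19 under DMSO (-0.24), because other probe sets of these genes differ. In other settings 54 changed sign, 0 past the threshold in either fit. Among named genes, 169 gene-setting pairs for SUP-B8 lost their call, against 27 for NALM-6, 57 for the interaction and 0 under DMSO. Alternatives for a pseudocount were not run because the values are log2. Signal near background limits what dim probe sets can show.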

Other observations

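The tests of the first 2 paragraphs were chosen after the results were seen. Genes that moved most in the arrays labelled NALM-6 often moved toward the level of the other line, a share compared only with that of all tested genes. Of 194 genes raised at least 2-fold there, 102 (52.6%) had been at least 1 log2 unit more abundant in the arrays labelled SUP-B8 under DMSO, against 10.4% of all tested genes. Of 91 genes lowered at least 2-fold, 75 (82.4%) had been at least 1 log2 unit less abundant there, against 9.66% of all genes. Both measures use the same DMSO arrays labelled NALM-6. Split between the measures, they gave genes chosen by a 2-fold difference alone. With replicate 1 of these for the response and replicate 2 for the level, the shares were 47.3% of 222 raised and 84.0% of 75 lowered genes. With their roles exchanged they were 56.7% of 171 and 78.0% of 100, each time from a single array. The shares of all genes in these splits were 10.1% and 10.8% for the raised and 9.99% and 9.36% for the lowered direction. All genes were not matched on their level in the DMSO arrays labelled NALM-6, although dim genes have more room to rise and abundant ones to fall. A gene dim in every array labelled NALM-6 was tested only through the arrays labelled SUP-B8. The split removes shared noise but neither of these limits, so a tendency beyond that of level was not shown.

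Heat-shock genes other than DNAJB1 were looked at because DNAJB1 led the falls, with a list of 17 written after that value was seen. Of 11 tested, 4 fell in the arrays labelled NALM-6 and 0 rose: HSPH1 (-1.01), CHORDC1 (-0.70), HSP90AA1 (-0.50) and HSPE1 (-0.43). Their median was -0.14, and limma called 0 of the 11 in the arrays labelled SUP-B8. HSPA4L, outside the 11 with every group below the array medians, was called the other way, higher in the arrays labelled NALM-6 (without the filter, adjusted p = 2.52e-04, and 2.74e-03 for the difference between the lines). The response differed between the lines for 4 of the 11, the call of FKBP4 being lost in 7 of 8 omissions of an array. Among 12 tested genes of a germinal-centre list, written after the comparison under DMSO was seen, 8 were less and 3 more abundant in the arrays labelled SUP-B8. ELL3 (-2.54) and the signalling adaptor GCSAM (-2.44) were lowest and MME (2.37) highest. With GSK126, 8 fell in the arrays labelled NALM-6, among them MYBL1 (-0.80) and LMO2 (-0.61), and CD38 (0.33) rose. In those labelled SUP-B8, BCL6 (0.34) rose and 0 fell by limma. The BCL6 call was lost without any of the 4 arrays of that label. In those labelled NALM-6 the call of ELL3 was lost in 2 of 8 omissions and that of MME in 3.

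Lists not described so far had no camera call in any comparison of the reported fit. BCL2 family genes fell in 6 of 15 and rose in 2 in the arrays labelled NALM-6, with BCL2A1 at -1.05 ± 0.11 and BIK at -0.62 ± 0.06 (adjusted p = 0.222). Cholesterol synthesis genes fell in 9 of 18 and rose in 2, HMGCS1 changing by -0.58 ± 0.06 (adjusted p = 0.0515, and adjusted p = 0.556 with an estimated correlation). This list was called without a filter (0.0202) and with the replicate block (0.0469). S100, annexin and actin-binding genes rose in 7 of 16 and fell in 2, with ANXA1 higher by at least 0.31 (adjusted p = 0.0703). Developmental transcription factors rose in 2 of 25 in the arrays labelled SUP-B8, ZIC2 and PITX1 (both levels below the array medians, not called without either GSK126 array of that label or with the mean of its probe sets), while in those labelled NALM-6 SOX7 (both levels below the array medians) and ZIC2 (-0.64 ± 0.08) were the falls and 2 rose (adjusted p = 0.616 and 0.717). Their median and mean in the arrays labelled SUP-B8, over the 25 tested of 71 listed, differed in sign (-0.00 and 0.04). Of the 14 genes listed as H3K27 and H3K4 counter-regulators, 13 were tested. In the arrays labelled NALM-6, 2 rose and 5 fell, with KMT2A at 0.36 ± 0.08 and KDM6A at -0.34 ± 0.09 (list, adjusted p = 0.378). In those labelled SUP-B8 limma called 0. KDM6A lost its call without DMSO replicate 2 or GSK126 replicate 1 labelled NALM-6. Of 39 HOX cluster genes 7 were tested, and 0 of these were called with GSK126 in either line. Without the filter on dim probe sets the HOX list as a whole also stayed uncalled, and its other members were not examined singly. T and NK cell markers in the arrays labelled NALM-6 had 2 rises and 2 falls of 14, with PRF1 at -1.05 ± 0.11, LCK at -1.04 ± 0.05 and GATA3 higher by at least 0.15. As means of their probe sets, PRF1 (-0.63) and SOX7 stayed called. Myeloid markers rose in 2 of 6 in the same arrays, AIF1 (0.28 ± 0.06) and ITGAX (0.31 ± 0.09), and both calls were lost without DMSO replicate 1 or GSK126 replicate 2 labelled NALM-6. That of ITGAX was also lost without DMSO replicate 2 and with the mean of its probe sets. Erythroid markers and fibroblast and endothelial markers had 0 calls with GSK126 among 9 and 8.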
